A study of Danio rerio with 28 samples.

How the data were processed

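Germ cells of zebrafish embryos at 3.5, 8 and 24 hpf and of fish at 2 weeks post fertilization were sorted singly into plates, per the labels. The embryos came from maternal-zygotic tdrd6a mutant mothers and from wild-type mothers that carried a germ cell GFP reporter. Per the labels' protocols, RNA of single cells was extracted with Trizol and amplified by in vitro transcription with CEL-seq, a 3' end counting method in which each well has its own barcode, and sequenced as paired ends on a NextSeq. BWA and the genome build Zv9 are named in the submitters' processing notes, with no version. How reads were counted, whether molecular identifiers were used, how cells and genes were selected and how cells were scaled are not given in the sources used here.

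The authors deposited 1 table for the series, and its unit was named signal, since each value is a whole number with 0.1 added (tolerance 1e-06), with no normalization stated. The number above 0.1 is called transcripts here; whether it counts molecules or reads is not known, and that cells were scaled or drawn to a common depth before genes were left out is inferred from the values and not stated. The lowest maximum over cells of any listed gene was 4. The design fixed in advance assumed normalized values tested as log2 plate means, and this was kept; negative binomial models were not applied, and limma voom on summed transcripts served as an alternative only. The table held 1017 genes and 1203 cells from 28 libraries, and each column was matched to a library by its name. Plates have 96 listed barcodes; 1 cell lay beyond them. Of the gene names 921 matched a symbol in either of the symbol tables used, 323 of them in the Ensembl symbols; all names are printed as the table gives them. No genome was used, so no coordinates are given. Near-identical copies, such as ribosomal protein, globin, keratin, titin and actin genes, may share reads, and values of single members are uncertain for that reason.

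Groups were genotype by stage, with 26 plates in 6 groups. The 2 week plate entered no test. A plate labelled with both 8 and 24 hpf, with 45 cells, was left out. Of mutant plate 1 at 8 hpf the first 48 barcodes are described as mutant and entered; the last 48, described as heterozygous, did not. The summed transcripts per plate ranged from 1027 to 32018, which sets the precision: in a plate of 2 cells 1 transcript in 1 cell weighs far more on a mean than in the largest plates, so plates were also weighted by their number of cells as an alternative.

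For each plate the deposited values were averaged over cells. Genes with a mean of at least 0.2 in at least 3 plates were tested, which kept 910 and left out 107. Limma 3.58.1 in R 4.3.3 was run on log2 of the mean plus 0.1 (0.2 over transcripts), with the 6 groups in 1 fit that left 20 residual degrees of freedom, so that small groups borrow the shared spread. Empirical Bayes moderation used the trend and robust options; p-values are two-sided, adjusted by Benjamini-Hochberg with a threshold of 0.05. Contrasts were genotype at each stage, stage within each genotype, and the change of the genotype difference between stages.

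Gene lists, fixed before the data were examined like the design, the main settings and the other settings listed below as alternatives, apart from those marked as later, covered germ plasm, Tudor and piRNA genes, maternal, first zygotic, pluripotency, epidermis and enveloping layer, neural, muscle, blood, macrophage and neutrophil, hatching gland, endoderm, mesoderm and notochord, cell cycle, ribosomal protein, mitochondrial, stress, p53 and migration genes. Of these 19 lists 16 had at least 2 tested genes and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 16. The blood list had 1 tested gene, hbbe3, and was described by its plate sums; the macrophage list had coro1a alone and the endoderm list no listed member. Some genes stand in more than 1 list, such as vasa, tdrd7, tbx16, sox3, krt4 and ccnb1. Germ plasm share, the share of cells with at least 3 germ plasm genes, and the mean pairwise Spearman correlation of germ plasm genes were computed per plate. The correlation used plates of at least 10 cells and genes detected in at least 20% of cells of the stage, and was set against 1000 random sets of matched mean. Plate summaries were compared with two-sided exact permutation tests in scipy 1.17.1.

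Named genes followed a fixed rule: germ plasm genes (6 with values), genes past the threshold whose plates did not overlap, and list members of smallest p. Values are followed through the alternatives for the 6 germ plasm genes, for 1 gene per other list and for called genes, and in stage comparisons for 5 genes each way and 1 per list. Genes with clone names were counted and left unnamed, except those named as chosen after their values were seen. Cells were clustered with scanpy 1.11.5 (20 principal components, 15 neighbours, leiden resolution 0.8), giving 10 clusters, which are named by number and leading genes. No doublet caller was run, since cells were sorted into single wells, and no cell was filtered beyond the authors' table. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were used.

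Alternatives were pseudocounts of 1 and 0.02, no filter, a plate mean of at least 1, plates rescaled to the same total, plates weighted by cells, each comparison fitted alone, plates of fewer than 10 cells left out, each plate left out in turn, heterozygous wells or 24 hpf wells of the mixed plate added, and the plate number as a block. Added later were limma voom on summed transcripts, rescaling without CABZ01111496.1, mutant plate 1 left out together with small plates, and clusters 7 and 8 alone. The germ plasm measures were also computed with other minimum gene numbers, with other detection minimums and without the most abundant gene.

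The limma step was tested on simulated data with 910 genes, of which 200 were changed, in 20 runs. Genes changed by 1 log2 unit in transcripts were recovered at 34.4% at 3.5 hpf, 30.5% at 8 hpf and 18.4% at 24 hpf, and genes changed by 2 units at 79.8%, 73.9% and 72.5%. The mean estimated fold for a change of 2 was 1.23, 1.22 and 1.22, owing to the added constant. Of the calls 5%, 10.9% and 2.5% were false, and with no change 0.1, 0.5 and 0.3 genes were called per run. A shifted list of 10 genes was found by camera in 20 of 20 runs at each stage, and an unchanged list was called in 0, 2 and 0 runs. The simulated genes varied independently between plates. The correlation estimated within the real lists was 0.456 for germ plasm, 0.495 for ribosomal protein and 0.718 for muscle genes. These runs therefore do not show how often camera at the preset correlation calls such correlated lists falsely.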

Results

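Primordial germ cells of zebrafish embryos, the precursors of eggs and sperm, were sorted one per well from offspring of maternal-zygotic tdrd6a mutant mothers and of wild-type mothers. Tdrd6a is a Tudor domain protein of the germ plasm, the maternally supplied RNA and protein granules that mark germ cells in this species. The title of the series asks how it coordinates the loading of germ plasm mRNAs into these cells. Each library was a plate of wells, and 26 plates with 1034 cells entered the comparisons. At 3.5 hours post fertilization (hpf) there were 5 wild-type plates with 205 cells and 5 mutant plates with 264 cells. At 8 hpf there were 4 wild-type plates with 101 cells and 4 mutant plates with 112 cells, and at 24 hpf 5 wild-type plates with 196 cells and 3 mutant plates with 156 cells. The smallest plates held 2, 4 and 6 cells.

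The table listed 1017 genes in 1203 cells. Its values stood at a floor of 0.1 or at a whole number above it, and this whole number is called transcripts here. A cell held a median of 424 transcripts over the listed genes, with a range of 156 to 855, and 77.9% of values were at the floor. Plate medians per cell lay between 351 and 399.5 in the wild type and 320 and 367 in the mutant at 3.5 hpf. They lay between 373 and 502 against 416 and 535 at 8 hpf, and between 440 and 627 against 525.5 and 634 at 24 hpf. Levels below are transcripts per cell as the mean over plates with SD. Fold changes are log2 differences of plate means with 0.2 added to the transcripts, which understates changes of low genes. All adjusted p-values of genes are two-sided limma tests adjusted by Benjamini-Hochberg over 910 genes. The replicates were plates that the labels do not state to be separate animals or clutches, so p-values measure only the spread between plates. The targeted gene, tdrd6a, was not analysed here.

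The first question was how much germ plasm mRNA the cells carried. The germ plasm list held vasa, nanos3, dnd, dazl, tdrd7, gra, ca15b and h1m among the tested genes, with piwil1 and piwil2 added to plate sums. It took 2.12% ± 1.23 (SD, n = 5) of transcripts in the mutant and 1.82% ± 1.16 (n = 5) in the wild type at 3.5 hpf. Shares of transcripts here and below are over the listed genes, not over all transcripts of a cell. At 8 hpf the share was 0.736% ± 0.389 (n = 4) against 1.67% ± 1.32 (n = 4), and at 24 hpf 0.439% ± 0.463 (n = 3) against 0.957% ± 0.567 (n = 5). The germ plasm share 3.5 hpf difference turned to −0.0863 without h1m and to −0.0452 without mutant plate 2. Most germ plasm transcripts at 3.5 hpf were of h1m, so the share there mainly followed that gene. The difference without h1m is one between far smaller shares. The germ plasm share 8 hpf difference was −0.357 without wild-type plate 2. Without wild-type plate 1 of 3.5 hpf, with 4 cells and a share of 3.85% (nearest plate 1.71%), the 3.5 hpf difference was larger. The differences did not exceed the spread between plates, with two-sided exact permutation p = 0.881, 0.343 and 0.196. Cells with at least 3 germ plasm genes detected made up 17.3% ± 4.67 against 22.2% ± 13.1 at 3.5 hpf, 43.3% ± 11 against 45.4% ± 21.8 at 8 hpf, and 16.9% ± 14.6 against 33.1% ± 15.2 at 24 hpf. Exact permutation p-values were 0.476, 0.8 and 0.214. The smallest Benjamini-Hochberg value over the 9 tests of germ plasm measures was 0.714. Without plates of fewer than 10 cells, the germ plasm positive cells 3.5 hpf difference was −10.4 percentage points and passed an unadjusted exact test. The germ plasm positive cells 8 hpf difference turned to 4.55 without wild-type plate 2 and to 3.32 without mutant plate 1.

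Germ plasm genes varied together from cell to cell at 8 and 24 hpf. At 8 hpf the mean pairwise Spearman correlation among vasa, nanos3, dnd, tdrd7, gra, ca15b and h1m was 0.355 ± 0.196 in the wild type and 0.191 ± 0.0807 in the mutant, over 3 plates of each. Random gene sets of matched level had medians of 0.0687 and 0.0474, and 100% of 1000 such sets lay below the germ plasm value in each genotype. At 24 hpf the pair detected widely enough, vasa and nanos3, correlated at 0.421 ± 0.132 (n = 5) in the wild type and 0.378 ± 0.248 (n = 3) in the mutant, also above 100% of random sets. At 3.5 hpf the detected pair was ca15b and h1m, with −0.0071 ± 0.0762 (n = 4) in the wild type and 0.0676 ± 0.160 (n = 5) in the mutant, above 49.6% and 84.1% of random sets. A mix of cells rich and poor in germ plasm transcripts can also make these genes vary together. Clusters 8, 7 and 6, which held the 24 hpf cells, had 8.308, 1.399 and 0.855 germ plasm transcripts per cell. The random sets were matched on mean only, so these values do not separate coordinated loading from such a mix. The genotypes did not differ beyond the spread between plates, with exact permutation p = 0.3, 0.821 and 0.452 at 8, 24 and 3.5 hpf. At 8 hpf the smallest p that 3 plates against 3 allow is 0.1. The germ plasm co-variation 24 hpf difference turned to 0.0855 without mutant plate 3. Changes of the genotype difference between stages gave exact p-values from 0.14 to 0.838 over the measures.

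**Figure D1:**
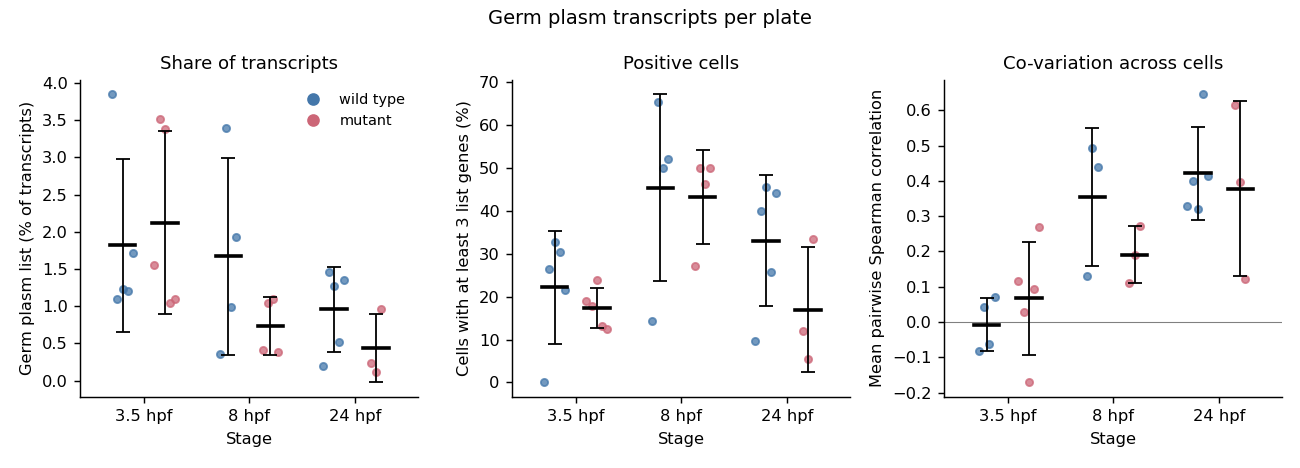
Germ plasm measures per plate by stage and genotype: share of transcripts in percent, cells with at least 3 germ plasm genes in percent, and mean pairwise Spearman correlation. Points are plates and bars are means with SD; the genotypes overlapped in each measure at each stage.

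At 3.5 hpf, in the blastula, zgc:113886 and zgc:100951 fell in the mutant. The first stood at 0.448 ± 0.378 transcripts per cell in the mutant (n = 5) and 1.44 ± 0.499 in the wild type (n = 5), a log2 change of −1.44 (SE 0.24) with an adjusted p of 9e-04. The second stood at 0.257 ± 0.2 against 0.838 ± 0.281, a log2 change of −1.25 (SE 0.22) with an adjusted p of 9e-04. Both were lower in the mutant mean, and plate 4 of the mutant overlapped the wild type for zgc:113886 with 1.115. These 2 were the genes past the threshold among 910, chosen for naming after their values were seen because they carry clone names. Both calls rested on the spread shared with the other stages, since adjusted p for zgc:113886, genotype 3.5 hpf, and for zgc:100951, genotype 3.5 hpf, was 0.226 with the 3.5 hpf plates alone in the fit.

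None of the 8 germ plasm genes passed at 3.5 hpf. The RNA helicase gene vasa stood at 0.0974 ± 0.0628 in the mutant and 0.195 ± 0.155 in the wild type, a log2 difference of −0.34 (SE 0.36). The oocyte linker histone gene h1m, by far the most abundant member, stood at 6.19 ± 3.89 against 5.52 ± 5.1 (log2 0.28, SE 0.40). The germ granule gene tdrd7 stood at 0.0916 ± 0.0431 against 0.177 ± 0.0741, gra at 0.0869 ± 0.0276 against 0.173 ± 0.0593, dazl at 0.0797 ± 0.0421 against 0.052 ± 0.0395 and dnd at 0.0391 ± 0.029 against 0.103 ± 0.101. Camera, a test of whether a list moves against all other genes, gave an adjusted p of 0.591 for the list over 16 lists.

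Among the 81 ribosomal protein genes at 3.5 hpf, 71 had a higher mutant mean, with a mean log2 difference of 0.23. None passed alone; rps16 had 0.413 ± 0.120 against 0.0973 ± 0.0609 (log2 1.05, SE 0.36, adjusted p = 0.55). Camera with its preset correlation gave an adjusted p of 6.38e-09, and the adjusted p was 0.443 with an estimated correlation. The 11 mitochondrially encoded genes leaned the same way in 9 members (mean log2 0.32), with mt-atp8 at 0.245 ± 0.227 against 0.0375 ± 0.0482; camera adjusted p was 0.00808, and 0.443 with an estimated correlation. For the mitochondrial list, genotype 3.5 hpf, the mean was 0.11 without plates of fewer than 10 cells and 0.17 without mutant plate 1, and adjusted p was 0.161 and 0.21. Of the 74 cells of that mutant plate, 24 fell into cluster 2, with a median of 128 genes and 87.84 mitochondrial transcripts per cell. The 8 egg-loaded maternal genes had a mean of 0.18 with 6 positive members, which turned to −0.035 without plates of fewer than 10 cells and 8 hpf mutant plate 1. The germ granule organizer gene buc had 0.624 ± 0.149 against 0.421 ± 0.123 (adjusted p = 0.642). Their camera adjusted p was 0.0417, and 0.443 with an estimated correlation. As shares of transcripts over the listed genes, ribosomal protein genes took 9.56% ± 1.15 against 7.16% ± 0.865 (n = 5 each). The exact permutation p was 0.0159, and 0.335 after adjustment over 74 such tests.

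The other lists passed no camera test at 3.5 hpf, with pluripotency genes lowest at an adjusted p of 0.0672. Their members nanog, pou5f3 and sox3 had negative differences, with pou5f3 at 0.461 ± 0.0714 against 0.777 ± 0.427. The T-box gene tbx16 stood at 0.0259 ± 0.0501 against 0.228 ± 0.298 (adjusted p = 0.55). Adjusted over the list alone, it passed as lower in the first zygotic and the mesoderm and notochord lists. Wild-type plate 1, with 4 cells, held 1.0 transcripts per cell of the mesoderm and notochord list (nearest plate 0.163). The mean log2 difference of that list went from −0.32 to −0.13 without plates of fewer than 10 cells and 8 hpf mutant plate 1. Cell cycle genes summed to 7.57 ± 1.21 against 9.24 ± 0.455 transcripts per cell, with an exact permutation p of 0.0079, the smallest that 5 plates against 5 allow, and 0.335 after adjustment. Mutant plate 1, with the cluster 2 cells, was lowest at 5.689, and the highest mutant plate had 8.738 against 8.75 in the lowest wild-type plate. The list's mean log2 difference went from −0.18 to −0.11 with plates rescaled to the same total. CCNA2 stood at 0.483 ± 0.233 against 0.656 ± 0.151. Single members of the stress (btg2, 0.643 ± 0.139 against 0.918 ± 0.216), p53 (mdm2, 0.0587 ± 0.0402 against 0.177 ± 0.193), epidermis (krt18, 0.0255 ± 0.0335 against 0.322 ± 0.531) and migration lists (akap12b, 0.0981 ± 0.0527 against 0.576 ± 0.811) did not pass. Of the macrophage and neutrophil list, coro1a alone was listed, at 0.007 against 0.014 per cell at 3.5 hpf and 0.012 against 0.016 at 24 hpf; the endoderm list had no listed member. In total 51 genes had an unadjusted p under 0.05, where 45.5 would by chance and the simulated runs with no change gave a mean of 41.6. Limma voom on summed transcripts called 3 genes.

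At 8 hpf, during gastrulation, no gene passed between genotypes (n = 4 plates each). Limma gave 67 genes at an unadjusted p under 0.05, against a mean of 85.6 in the simulated runs with no change. Limma voom called 0 genes. Of the 16 lists, germ plasm genes had the lowest mean difference on the deposited scale. The germ cell marker ca15b stood at 0.134 ± 0.112 against 0.956 ± 0.837 (log2 −1.52, SE 0.45) and vasa at 0.392 ± 0.316 against 1.18 ± 0.591 (log2 −1.31, SE 0.41), each with an adjusted p of 0.325. For tdrd7 the values were 0.423 ± 0.081 against 0.875 ± 0.657, for dnd 0.326 ± 0.268 against 0.701 ± 0.767, and for gra 0.342 ± 0.128 against 0.441 ± 0.202. All 8 tested members had a negative difference (mean log2 −0.63); adjusted over the list alone, 2 of 8 were lower, vasa and ca15b.

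Camera placed the germ plasm list below the other genes at 8 hpf with an adjusted p of 0.00105, which was 0.755 with an estimated correlation. For the germ_plasm list, genotype 8 hpf, adjusted p was 0.33 without mutant plate 1 and 0.201 without wild-type plate 2. The mean was −0.34 without mutant plate 1 and all plates of fewer than 10 cells, at an adjusted p of 0.0104. The mean stayed negative under each scaling; voom moved the median difference of all genes from 0.00 to 0.19 at 8 hpf and to −0.14 at 24 hpf.

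Ribosomal protein and muscle genes had higher mutant means at 8 hpf, which depended on the plates kept. Of 81 ribosomal protein genes 63 were positive (mean log2 0.32; 2 higher when adjusted over the list alone), with a camera adjusted p of 3.09e-07 and 0.755 with an estimated correlation. All 10 muscle genes were positive (mean 0.41), with the muscle creatine kinase gene ckma at 0.194 ± 0.319 in the mutant and not detected in the wild type; camera adjusted p was 0.0064, and 0.755 with an estimated correlation. For the ribosomal_protein list, genotype 8 hpf, the mean turned to −0.0467 without mutant plate 1, but was 0.28 without that plate and the plates of fewer than 10 cells (adjusted p = 0.000175) and 0.67 without those small plates alone. For the muscle list, genotype 8 hpf, it was 0.02 without mutant plate 1 and 0.09 without it and the small plates, with adjusted p of 0.664 and 0.959. Muscle transcripts in mutant plate 1 summed to 5.312 per cell against at most 0.5 in the other mutant plates, and erythroid globin transcripts to 5.354. The other 48 barcodes of that plate, described as heterozygous and not in the comparison, held 5.729 globin transcripts per cell. Over the 4 mutant plates the erythroid list averaged 1.35 ± 2.67, and it was not detected in the 4 wild-type plates.

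**Figure D2:**
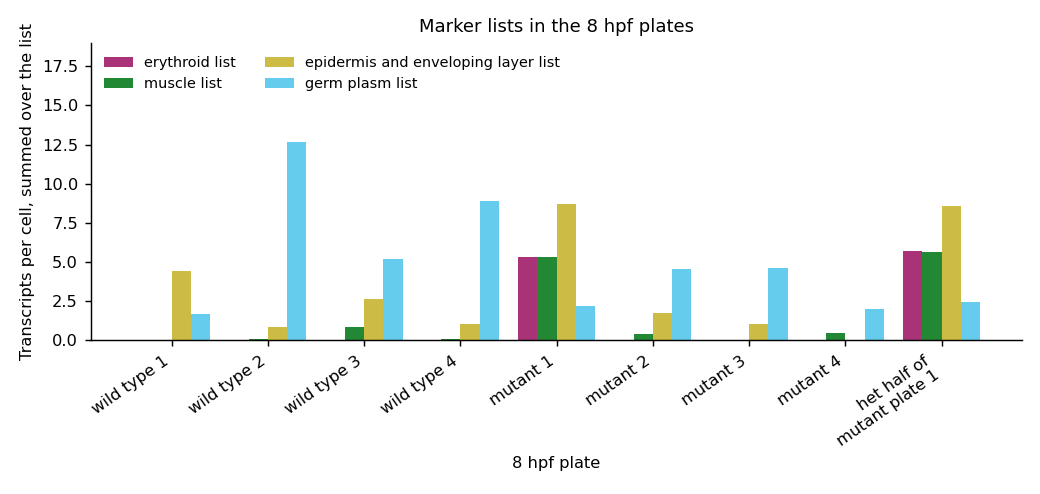
Transcripts per cell summed over 4 marker lists in each 8 hpf plate, with the heterozygous wells of mutant plate 1 as a separate group; bars are plate values. Mutant plate 1 and its heterozygous wells held 5.354 and 5.729 erythroid transcripts per cell, while the 4 wild-type plates held 0.

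In the remaining lists at 8 hpf camera adjusted p was 0.0952 for mitochondrial genes (10 of 11 negative, mean −0.36, and 0.031 without mutant plate 1 and the small plates) and 0.106 or more elsewhere. Among them mt-atp6 stood at 2.57 ± 1.06 against 4.79 ± 2.32. The mitochondrial chaperonin gene hspe1 stood at 0.309 ± 0.172 against 0.0604 ± 0.0767 (adjusted p = 0.325) and was 1 higher stress gene when adjusted over the list alone. Values of msgn1 were 0.114 ± 0.0936 against 0.234 ± 0.110, of id3 0.173 ± 0.130 against 0.0608 ± 0.0644, and of nanog 0.0513 ± 0.0402 against 0.122 ± 0.0817. The hatching enzyme gene he1b, the epidermal gene icn and the neuronal gene elavl3 were not detected in the wild type and averaged 0.162 ± 0.323, 0.115 ± 0.229 and 0.0521 ± 0.104 in the mutant, again with mutant plate 1 among the plates.

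At 24 hpf, col2a1a rose in the mutant. This gene encodes the type II collagen chain of notochord sheath and cartilage. It stood at 0.401 ± 0.187 transcripts per cell in the mutant (n = 3) and 0.0461 ± 0.037 in the wild type (n = 5), a log2 change of 1.26 (SE 0.20) with an adjusted p of 0.000566. The 3 mutant plates had 0.278, 0.310 and 0.617 and the highest wild-type plate 0.0976. It was the 1 gene of 910 that passed. An unadjusted p under 0.05 was reached by 21 genes, against a mean of 21.2 in the simulated runs with no change. Limma voom called 1 gene. The call for col2a1a, genotype 24 hpf, ended at an adjusted p of 0.771 with a log2 difference of 0.97 when the 24 hpf wells of a plate labelled with 2 stages joined the wild type. It ended at 0.0919 with the 24 hpf plates alone in the fit, and the difference was 0.08 in the cells of cluster 8 and 1.95 in those of cluster 7.

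The mesoderm and notochord list, tested through col2a1a, msgn1 and tbx16, was higher in the mutant at 24 hpf (1 of 3 genes rose, also adjusted over the list alone; mean log2 0.64). Camera adjusted p was 2.74e-06 and remained 0.00451 with an estimated correlation, the only genotype list past both. The paraxial mesoderm gene msgn1 stood at 0.101 ± 0.0938 against 0.00351 ± 0.00785. Summed over the list, mutant plates held 0.711 ± 0.208 transcripts per cell and wild-type plates 0.097 ± 0.076, with an exact permutation p of 0.0179, the smallest that 3 plates against 5 allow, and 0.335 after adjustment. The estimated-correlation p for the mesoderm_notochord list, genotype 24 hpf, was 0.0807 without mutant plate 3, and the preset p was 0.689 in cluster 8 alone. The list includes col2a1a, the gene called above, so it is not separate support. The 24 hpf wells of the mixed plate, outside the comparison, held 0.9 transcripts per cell of the list. Mutant plates 1, 2 and 3 held 0.571, 0.611 and 0.95.

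**Figure D3:**
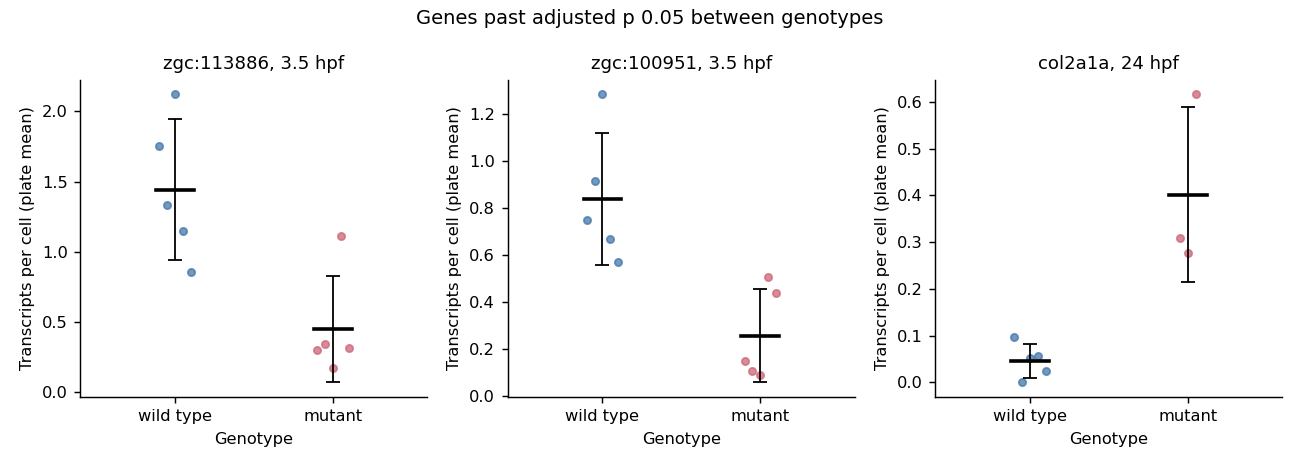
Plate means of zgc:113886 and zgc:100951 at 3.5 hpf and of col2a1a at 24 hpf, in transcripts per cell, by genotype. Points are plates and bars are means with SD; for col2a1a the lowest mutant plate (0.278) lies above the highest wild-type plate (0.0976).

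Germ plasm genes had lower mutant means at 24 hpf in 7 of 8 members, with a mean log2 difference of −0.54 that stayed negative under each scaling. None passed alone. The germline translational repressor nanos3 stood at 1.35 ± 1.56 against 3.02 ± 2.3, vasa at 0.251 ± 0.116 against 0.788 ± 0.384 (log2 −1.06, SE 0.42), and gra at 0.0173 ± 0.0167 against 0.162 ± 0.0833 (log2 −0.71, SE 0.25), each with an adjusted p of 1. Values were 0.115 ± 0.126 against 0.325 ± 0.168 for dnd and 0.139 ± 0.184 against 0.250 ± 0.0649 for h1m. Camera adjusted p was 7.34e-05, and 0.189 with an estimated correlation. For the germ_plasm list, genotype 24 hpf, the preset p was 0.0608 in cluster 8 alone and 0.832 in cluster 7 alone, with means of −0.32 and −0.09. The Tudor and piRNA list (GTSF1L, tdrd7 and vasa, the last 2 also in the germ plasm list) was lower in all 3 members, with a mean of −0.53, a camera adjusted p of 0.0204 and 0.189 with an estimated correlation.

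All 10 muscle genes had a higher mutant mean at 24 hpf (mean log2 0.37), none past the threshold; tnnc2 stood at 0.159 ± 0.105 against 0.0741 ± 0.0592. Camera adjusted p was 3e-04, and 0.435 with an estimated correlation. For the muscle list, genotype 24 hpf, it was 0.084 with the 24 hpf wells of the mixed plate added and 0.454 without mutant plate 2. Erythroid transcripts averaged 0.343 ± 0.285 against 0.036 ± 0.041 (exact permutation p = 0.0714) and epidermal transcripts 5.82 ± 3.88 against 3.95 ± 1.6. Mutant plate 3 held 0.017 erythroid and 1.4 epidermal transcripts per cell, against 0.548 and 7.405 in plate 1 and 0.463 and 8.648 in plate 2. The other lists had camera adjusted p of 0.17 or more: mt-atp8 stood at 0.280 ± 0.175 against 0.0705 ± 0.0426, hsp90aa1.2 at 0.118 ± 0.0407 against 0.327 ± 0.141, apoeb at 0.446 ± 0.356 against 0.158 ± 0.198, rps29 at 3.16 ± 0.748 against 2.12 ± 0.550, pcna at 2.06 ± 0.735 against 1.40 ± 0.330 and ccng1 at 0.734 ± 0.363 against 0.450 ± 0.287.

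Cells of 24 hpf fell into clusters 6, 7 and 8, except for 1 wild-type cell in cluster 4. Cluster 8 was led by nanos3, at 4.97 transcripts per cell against 0.638 in all other cells, cluster 7 by sst2, fos and icn2, and cluster 6 by the titin genes ttna and ttnb. Clusters 6, 7 and 8 made up 27.3% ± 27.8, 44.3% ± 22.5 and 28.4% ± 34 of mutant cells (n = 3) and 15.9% ± 26.6, 39.3% ± 23 and 44.4% ± 27.5 of wild-type cells (n = 5). Exact permutation p-values were 0.536, 0.75 and 0.5. Wild-type plate 1 and mutant plate 2 had most of their cells in cluster 6, so the mix varied more between plates than between genotypes.

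**Figure D4:**
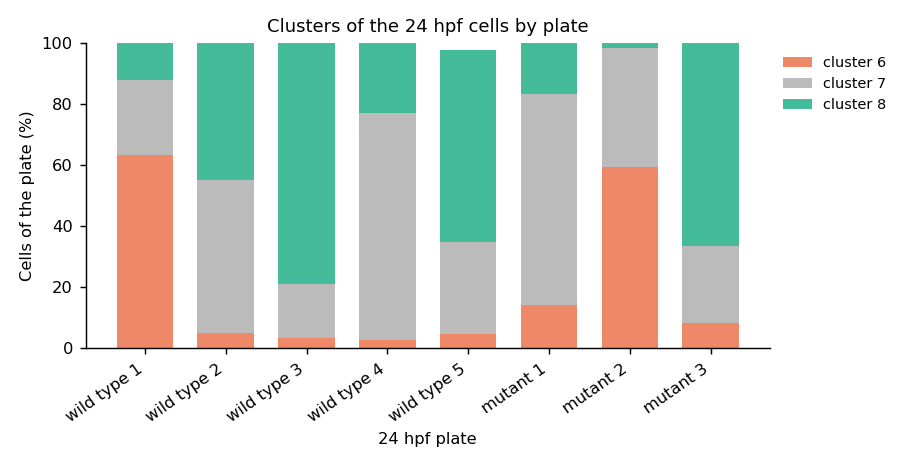
Percent of cells in clusters 6, 7 and 8 for each 24 hpf plate, as stacked bars. Cluster 8, led by nanos3, averaged 44.4% in wild-type and 28.4% in mutant plates, with plates of each genotype at low and high shares.

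From 3.5 to 8 hpf, when maternal mRNA is cleared and the embryo's own genes are switched on, all 8 egg-loaded maternal genes fell in the wild type and in the mutant, under each scaling. In the wild type cldnd went from 1.68 ± 0.451 (n = 5) to 0.0770 ± 0.0689 (n = 4; log2 −2.76, SE 0.24), and cth1 from 1.14 ± 0.498 to not detected (adjusted p = 2.19e-10). In the mutant cldnd went from 2.52 ± 0.600 (n = 5) to 0.0235 ± 0.028 (n = 4; log2 −3.59, SE 0.24, adjusted p = 8.94e-13) and the meiotic cyclin gene ccna1 from 1.92 ± 0.854 to 0.0208 ± 0.0417. The list's mean was −1.99 and −2.32. Camera adjusted p was 3.52e-07 in the wild type and 0.099 with an estimated correlation, against 8.1e-09 and 0.0448 in the mutant. The pluripotency factor gene nanog fell from 1.56 ± 0.116 to 0.122 ± 0.0817 in the wild type and from 1.21 ± 0.377 to 0.0513 ± 0.0402 in the mutant; with pou5f3 it made 2 of 3 list members falling in each. Camera adjusted p of that list was 0.046 (0.242 with an estimated correlation) and 0.0621.

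Germ plasm genes split over the same interval. In the wild type vasa, nanos3, dnd, tdrd7 and gra rose, 5 of 8 (3 under voom), while h1m fell from 5.52 ± 5.1 to 0.612 ± 0.225 (log2 −2.53, SE 0.43); vasa went from 0.195 ± 0.155 to 1.18 ± 0.591 (log2 1.78, SE 0.39, adjusted p = 0.000517). In the mutant nanos3, tdrd7 and gra rose, 3 of 8, and h1m fell from 6.19 ± 3.89 to 0.556 ± 0.236. Adjusted over the list alone, 5 and 4 rose. The list mean was 0.70 in the wild type, with a camera adjusted p of 0.046 and 0.582 with an estimated correlation. In the mutant it was 0.21, at a camera adjusted p of 0.469, which turned to −0.014 with plates rescaled to the same total and was 0.41 under voom. Without mutant plate 1 and plates of fewer than 10 cells it was 0.55, with 5 genes rising as in the wild type (0.74). Of the first zygotic list 3 of 6 rose in the wild type and 2 in the mutant. The lipoprotein gene apoeb went from 0.230 ± 0.104 to 1.71 ± 1.04 and from 0.133 ± 0.0587 to 1.52 ± 0.777. Values of tbx16 went from 0.228 ± 0.298 to 0.616 ± 0.187 and from 0.0259 ± 0.0501 to 0.605 ± 0.0732.

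Other lists moved in part from 3.5 to 8 hpf. Ribosomal protein genes rose in 18 of 81 in the wild type and 22 in the mutant, with 1 falling in each. In the mutant 12 rose and 4 fell after rescaling, and 33 rose under voom; in the wild type the counts rising were 14 and 15. Camera adjusted p was 3.09e-06 and 1.53e-06, and 0.582 and 0.683 with an estimated correlation. In cell cycle genes 4 of 11 fell in each genotype, among them rrm2, a subunit gene of ribonucleotide reductase (2.58 ± 1.1 to 0.202 ± 0.170 in the wild type). Of 9 stress genes 3 rose and 2 fell in the wild type, and 5 rose and 2 fell in the mutant; hspa5 fell from 0.967 ± 0.280 to 0.0991 ± 0.0864 in the mutant and btg2 from 0.918 ± 0.216 to 0.0736 ± 0.0702 in the wild type. In the migration list ezrb fell in each genotype, and in the hatching gland list xbp1 did. The adhesion gene epcam fell from 1.04 ± 1.24 to 0.0676 ± 0.060 in the wild type, where krt4 and krt5 rose, and from 1.38 ± 0.983 to 0.0697 ± 0.0656 in the mutant. Of the Tudor and piRNA list tdrd7 rose and GTSF1L fell in each genotype, and vasa rose in the wild type. In the mutant 2 of 10 muscle genes rose, actc1b and ckma, and 0 without plates of fewer than 10 cells and mutant plate 1, which carried the muscle transcripts described above. No neural gene passed in either genotype on the deposited scale. Under voom 1 rose in each, and 1 fell in the wild type without plates of fewer than 10 cells and mutant plate 1. Under voom 4 of 6 first zygotic, 3 of 10 epidermal and 4 of 10 muscle genes rose in the mutant, and vasa did too. The unnamed transcript CABZ01111496.1, singled out after its values were seen, went from 7.34 ± 6.11 to 113 ± 54.3 transcripts per cell in the wild type (log2 4.28, SE 0.87) and from 3.99 ± 5.61 to 107 ± 103 in the mutant (log2 5.14, SE 0.87). At 8 hpf it took 24.5% ± 10.7 and 22.4% ± 19.6 of transcripts over the listed genes.

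Over all genes 316 of 910 passed between 3.5 and 8 hpf in the wild type, 106 higher and 210 lower, and 290 in the mutant, 107 higher and 183 lower. The lower genes shared 154 between genotypes where 42.2 would overlap if the lists were independent, the higher genes 60 against 12.5, and 0 went opposite ways. Log2 changes correlated across genes at Pearson r = 0.873, although genes are not independent replicates. For stage mut 3.5 to 8 hpf the split was 75 higher and 266 lower with plates rescaled to the same total, and the count was 472 with plates weighted by their number of cells. The median change of all genes moved from −0.02 to −0.27 under voom in the wild type and from 0.01 to −0.21 under rescaling in the mutant, so changes of that size carry no direction.

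From 8 to 24 hpf ribosomal protein genes rose together, in 77 of 81 in the wild type and 69 of 81 in the mutant, with 0 falling under any scaling. In the wild type rpl27 went from 0.448 ± 0.243 (n = 4) to 3.54 ± 0.486 (n = 5; log2 2.61, SE 0.41). In the mutant rpl35a went from 0.888 ± 0.891 (n = 4) to 4.32 ± 0.877 (n = 3; log2 2.5, SE 0.48) and rpsa from 1.31 ± 1.45 to 4.33 ± 0.543. Their list means were 1.62 and 1.39, with camera adjusted p of 2.43e-29 and 1.7e-28, and 0.29 and 0.317 with an estimated correlation. The mutant count was 44 with plates rescaled to the same total, 28 without CABZ01111496.1 and 40 under voom. The fatty acid binding protein gene fabp3 rose from 0.0640 ± 0.054 to 1.48 ± 0.420 in the wild type (log2 2.66, SE 0.37, adjusted p = 6.96e-06) and from 0.210 ± 0.402 to 1.61 ± 0.487 in the mutant (log2 2.5, SE 0.42). Of the falling genes tbx16 went from 0.616 ± 0.187 to not detected in the wild type and from 0.605 ± 0.0732 to 0.0221 ± 0.024 in the mutant. The spliceosomal RNA U1 went from 7.83 ± 4.80 to 0.506 ± 0.256 and from 2.40 ± 1.59 to 0.318 ± 0.241.

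Of 8 germ plasm genes ca15b, gra and tdrd7 fell from 8 to 24 hpf in the wild type, with tdrd7 from 0.875 ± 0.657 to 0.167 ± 0.1 (log2 −1.33, SE 0.32, adjusted p = 0.00148). In the mutant gra fell, from 0.342 ± 0.128 to 0.0173 ± 0.0167 (log2 −1.29, SE 0.27, adjusted p = 0.00167). The counts gave no fixed contrast between genotypes: under voom 3 genes fell in the wild type and 4 in the mutant, and without 8 hpf mutant plate 1 and plates of fewer than 10 cells 3 and 2. List means were −0.57 and −0.47, with camera adjusted p of 0.0483 and 0.0394, and 0.374 and 0.563 with an estimated correlation. In the Tudor and piRNA list tdrd7 alone fell, in the wild type, and under voom 1 gene fell in the mutant too. Differentiation markers rose in part: 3 of 4 neural genes in the wild type (elavl3 from not detected to 0.235 ± 0.144) and 1 in the mutant (tubb5), 4 and 2 of 10 epidermal genes (icn from not detected to 0.406 ± 0.351 in the wild type), and 2 of 10 muscle genes, the titin genes ttna and ttnb, in each genotype. Without 8 hpf mutant plate 1 and plates of fewer than 10 cells 7 muscle genes rose in the wild type and 6 in the mutant, 5 and 4 epidermal genes, and 4 and 2 neural genes. Under voom 1 neural gene rose in the wild type and 0 in the mutant, and 1 muscle gene in each; 1 epidermal gene rose in the wild type, and no epidermal gene passed in the mutant under voom or after rescaling. Values of ttna went from 0.0102 ± 0.0204 to 0.849 ± 0.830 and from 0.0729 ± 0.146 to 1.45 ± 0.975. Among 24 hpf cells these markers lay mostly outside cluster 8. Clusters 6, 7 and 8 held 7.855, 3.341 and 1.161 muscle, 7.0, 8.509 and 1.224 epidermal, and 1.0, 1.538 and 0.315 neural transcripts per cell. Their germ plasm transcripts were 0.855, 1.399 and 8.308 per cell. No stage comparison was run within cluster 8, so these rises are not shown for cells rich in germ plasm transcripts. The tetraspanin gene cd63 of the hatching gland list rose in each genotype on the deposited scale, and no member of that list did in the mutant after rescaling.

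In the mesoderm and notochord list msgn1 and tbx16 fell in the wild type, while in the mutant tbx16 fell and col2a1a rose. Of the mitochondrial genes 3 of 11 rose in the mutant, with mt-atp6 from 2.57 ± 1.06 to 10.1 ± 4.56, and 0 in the wild type, where mt-atp6 went from 4.79 ± 2.32 to 9.17 ± 4.31 (adjusted p = 0.0744). This contrast did not hold without 8 hpf mutant plate 1 and plates of fewer than 10 cells, where 2 rose in the mutant and 5 in the wild type; after rescaling and under voom 1 rose in the mutant. In the wild type hsp90aa1.1 and hspe1 rose among stress genes, pou5f3 and nanog fell, and tpx2 was 1 cell cycle gene that fell. Without 8 hpf mutant plate 1 and plates of fewer than 10 cells 3 stress genes rose in the wild type and 2 in the mutant. In the mutant hspb1 fell from 1.25 ± 0.947 to 0.179 ± 0.163, and no pluripotency or cell cycle gene passed on the deposited scale. Under voom 3 cell cycle genes fell in the wild type, and 2 pluripotency and 4 cell cycle genes in the mutant; in the mutant it was 1 and 3 without 8 hpf mutant plate 1 and plates of fewer than 10 cells. Among the 3 migration genes akap12b fell in the wild type and none passed in the mutant, where 1 fell under voom and without those plates. No p53 or maternal gene passed between 8 and 24 hpf in either genotype on the deposited scale, but 3 maternal genes fell in the wild type and 2 in the mutant under voom, and 1 in each without the plates named above. For the first zygotic list, apoeb and tbx16 fell in each.

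In the wild type 282 of 910 genes passed between 8 and 24 hpf, 219 higher and 63 lower, and in the mutant 169, 145 higher and 24 lower. The genotypes shared 132 higher genes where 34.9 would overlap if the lists were independent and 19 lower against 1.7, with 0 opposite and r = 0.828 across genes. For stage wt 8 to 24 hpf the split was 150 to 131 without CABZ01111496.1 and 175 to 138 under voom. For stage mut 8 to 24 hpf it was 81 to 28 after rescaling, 59 to 48 without CABZ01111496.1 and 67 to 133 under voom. The median change of all genes moved from 0.12 to −0.18 under voom in the wild type and from 0.12 to −0.42 in the mutant, so the higher calls are relative to the deposited scale. The mutant count fell to 53 without plate 1 of the 24 hpf mutant and to 8 with these plates alone in the fit.

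The genotype difference itself was compared between stages. No gene changed its genotype difference from 3.5 to 8 hpf or from 8 to 24 hpf by limma, with 46 and 39 genes at an unadjusted p under 0.05 and 0 by voom in each. From 3.5 to 8 hpf the germ plasm genes (mean log2 −0.50, camera adjusted p = 0.0269), the maternal genes (−0.33, 0.0269) and the mitochondrial genes (−0.68, 0.000554) shifted below the other genes, and each had an adjusted p of 0.844 with an estimated correlation. Without mutant plate 1 and plates of fewer than 10 cells these means were −0.18, 0.015 and −0.08, the maternal one turned. From 8 to 24 hpf the mesoderm and notochord genes shifted up (0.70, camera adjusted p = 0.00478; 0.107 with an estimated correlation). Ribosomal protein genes shifted down (−0.24, 0.00478) and mitochondrial genes up (0.47, 0.0427), each at 0.828 with an estimated correlation; the mitochondrial mean was 0.09 without those plates. For the ribosomal_protein list, genotype by stage 24 minus 8 hpf, the mean turned to 0.13 without mutant plate 1 alone, at an adjusted p of 0.983, so this shift depended on 1 plate. Directions of the 6 list shifts held under each scaling.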

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

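Of the tests below, the spread between wells of 8 hpf mutant plate 1, its contrast with the heterozygous wells and with later cells, the limma fit within cluster 7 and the germ plasm share within cluster 8 were chosen after the results were seen; the difference of col2a1a within clusters 7 and 8 and the tests of a later collection time and of the cluster mix at 3.5 hpf were written before.

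Single plates stood apart from their group by a gap rule in 20 flags over 125 sets of plates. The rule flags about 1 in 20 sets of independent, normally distributed values, which would be 6.2. The sets reuse the same plates in related measures, some of low counts, so the excess over 6.2 cannot be interpreted. Wild-type plate 1 at 3.5 hpf, with 4 cells, had a germ plasm share of 3.85% (nearest plate 1.71%), 15.25 germ plasm transcripts per cell, 5.5 epidermal and 1.0 mesoderm transcripts per cell. Mutant plate 1 at 8 hpf had 27.1% germ plasm positive cells (nearest 46.2%), 5.354 blood transcripts per cell (nearest 0.056), 5.312 muscle (nearest 0.5) and 2.604 hatching gland transcripts (nearest 0.192). Mutant plate 4 at 8 hpf, with 2 cells, had 0.0 migration transcripts, and wild-type plate 1 had 1.857 (nearest 1.0). Wild-type plate 3 at 8 hpf, with 6 cells, had 0.833 muscle transcripts per cell (nearest 0.08).

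At 24 hpf wild-type plate 1 had 6.854 muscle transcripts per cell (nearest 2.3) and a median of 231 genes per cell (nearest 240). Wild-type plate 2 had 0.6 migration and 1.0 p53 transcripts per cell, plate 3 had 3.684 hatching gland transcripts (nearest 0.683), plate 4 a germ plasm correlation of 0.646 (nearest 0.413), and plate 5 a ribosomal protein share of 27.13% (nearest 31.73%). At 3.5 hpf mutant plate 5 held 3.91% of its transcripts in CABZ01111496.1 (nearest 1.16%), and mutant plate 4 had 1.115 transcripts of zgc:113886 per cell (nearest 0.343).

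The genotype difference changed between stages for 6 list tests at the preset correlation. From 3.5 to 8 hpf these were germ plasm (adjusted p = 0.0269), maternal (0.0269) and mitochondrial genes (0.000554), and from 8 to 24 hpf mesoderm and notochord (0.00478), ribosomal protein (0.00478) and mitochondrial genes (0.0427). None held with an estimated correlation.

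Signals also appeared in wells outside the comparisons. The heterozygous wells of mutant plate 1 held 5.729 blood transcripts per cell. The 24 hpf wells of the mixed plate held 3.1 blood transcripts per cell, where the highest 24 hpf wild-type plate had 0.098, and 0.625 col2a1a transcripts per cell against at most 0.098.

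Blood, muscle and epidermis transcripts in 8 hpf mutant plate 1 were weighed first. The tdrd6a genotype as their cause is argued against by the mutant wells holding −0.334 muscle transcripts per cell relative to the heterozygous wells of the same plate, with 5.35 and 5.73 blood and 8.71 and 8.58 epidermal transcripts in the mutant and heterozygous wells, and hbae3, krt4 and actc1b at 1.42, 4.44 and 1.44 against 1.67, 4.71 and 1.44. Single cells of a later stage are argued against by the spread between wells: the variance of the muscle sum was at most 1.59 times its mean in either set of wells, whereas in the 3 plates of 24 hpf with at least 4 muscle transcripts per cell it was at least 9.31 times. This holds for muscle. The blood sum cannot be told apart, with 1.967 and 2.018 times in the plate against 1.36 times and more at 24 hpf. The 24 hpf plate with 1.36 held only 0.463 blood transcripts per cell, so the levels compared were unlike. RNA spread over the wells of the plate predicts such an even level and may be the source, with the value of 1.59, while where such RNA came from stays open.

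Higher col2a1a and lower germ plasm genes at 24 hpf in the mutant were weighed next. A larger share of somatic cells was set to predict a difference under 0.1 within cluster 7. There col2a1a stood at 1.02 ± 1.09 (n = 3) in the mutant and 0.055 ± 0.087 (n = 5) in the wild type. The difference was 0.961 (limma adjusted p = 0.00031, no plates overlapped, 0.335 without mutant plate 3). So the share of cluster 7 cells alone did not account for it. Other somatic cells within cluster 7 cannot be told apart from a change per cell. The gene was used in the clustering and was among those that led cluster 7 (0.468 per cell against 0.042 in all other cells). Mutant plate 3 had the most col2a1a (0.617) with 66.7% cluster 8 cells, and wild-type plate 1, with 12.2%, had 0.0976. Another value set in advance, more col2a1a in each mutant than in each wild-type plate within cluster 8, was not met (0.0 and 0.05 against up to 0.037), so the difference lies in other cells; a subtype within cluster 7 stays open, as the 24 hpf wells of the mixed plate, called wild type, held 0.625 per cell with 38 of 40 in that cluster. For the germ plasm list a smaller share of cluster 8 cells cannot be told apart from lower levels per cell: the ratio of mutant to wild type was 0.443 within cluster 8 (exact permutation p = 0.107) and 0.458 over all cells, with mutant plate 2 holding 1 such cell, and 0.613 over plates of at least 5 such cells; the genotype itself stays open.

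Lower zgc:113886 and zgc:100951 at 3.5 hpf in the mutant were weighed last. A later collection of mutant embryos would lower the genes that fall by 8 hpf. The median genotype difference of 152 such genes was −0.054 (quartiles −0.2 and 0.144, 88 negative and 0 as low as the pair). This cannot decide it, since these genes were picked by a fall in both genotypes in the same plates. A gene already low in the mutant at 3.5 hpf would more often be missed. The 8 maternal genes, listed in advance, had a mean difference of 0.18 at 3.5 hpf. It was −0.035 without plates of fewer than 10 cells and 8 hpf mutant plate 1. A different mix of cells cannot be told apart: in the largest of 7 clusters of 3.5 hpf cells, with 97 cells, the difference nearer to 0 was −0.973 (zgc:113886 −1.28), but only 2 plates of each genotype had enough cells, where the smallest exact p is 0.333. An earlier collection of mutant embryos was not tested. At 3.5 hpf first zygotic genes summed to 0.438 ± 0.186 transcripts per cell in the mutant and 0.82 ± 0.464 in the wild type. CABZ01111496.1, which rose by 8 hpf, stood at 3.99 ± 5.61 against 7.34 ± 6.11. Neither exceeded the spread between plates (unadjusted exact permutation p = 0.151 and 0.286), so this stays open. The genotype and a difference between mothers also stay open and untested.

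Other splits of the same plates were compared with the real ones by their number of genes past the threshold. Chance is an unlikely cause for 3 stage comparisons, where 100 of 126 possible splits were counted. Only 1 of the 100, the real one, gave as many genes for wild type 3.5 to 8 hpf (316, highest other 258), mutant 3.5 to 8 hpf (290, 206) and wild type 8 to 24 hpf (282, 190). For mutant 8 to 24 hpf 2 of 35 splits gave as many (169, highest other 222), so this count alone cannot exclude chance; the larger one kept most plates with their stage and set mutant plate 1 of 8 hpf with the 24 hpf plates against the other 8 hpf plates. Of these genes 132 of the 145 higher and 19 of the 24 lower were shared with the separate wild-type plates, where 34.9 and 1.7 would overlap if independent. This overlap does not measure chance, since genes move together and both comparisons come from the same fit. Ribosomal protein genes alone made up 69 of the higher genes in the mutant and 77 in the wild type. Chance cannot be excluded for genotype at 3.5 hpf (9 of 100 splits, 2 genes, highest other 8) and at 24 hpf (16 of 56, 1, 48). The counts decide nothing for genotype at 8 hpf (35 of 35, highest other 25) and the changes of the genotype difference (100 of 100 each, highest other 1 and 44), since with 0 genes in the real split each split gives as many. The split with 48 genes joined mutant plates 1 and 2 with wild-type plate 1, which points to the cell mix of the plates rather than genotype. These plates had the lowest shares of cluster 8 cells (16.67%, 1.85% and 12.2%, with 22.86% or more in the others). They had the highest muscle sums (4.929, 5.833 and 6.854 per cell, at most 2.3 in the others). Their epidermal sums were also highest (7.405, 8.648 and 6.171, at most 4.837 in the others).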

How the results depend on the processing

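Limma voom, rescaling without CABZ01111496.1, the joint removal of mutant plate 1 and small plates, and clusters 7 and 8 alone were chosen after the data were seen. Low depth limits single genes: most levels are below 1 transcript per cell. The cause of the changes below was not tested, except where fewer genes or plates were tested by construction.

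Counts of genes moved by over 1.5 times as follows. For genotype 24 hpf, 3 passed with no filter, 2 in cluster 7 alone, and 0 with a plate mean of at least 1, with its groups alone, with the mixed plate's 24 hpf wells or in cluster 8 alone. For genotype 3.5 hpf, 1 passed with a plate mean of at least 1, 0 with its groups alone and 3 by voom. With a plate mean of at least 1, 104 passed for stage wt 3.5 to 8 hpf, 113 for stage mut 3.5 to 8 hpf and 137 for stage wt 8 to 24 hpf, where fewer genes were tested. Weighting by cells gave 472 for stage mut 3.5 to 8 hpf. For stage mut 8 to 24 hpf, 109 passed after rescaling, 107 without CABZ01111496.1 and 8 with its groups alone.

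Leaving out each plate gave 2 to 2 genes for genotype 3.5 hpf, 0 to 2 for genotype 8 hpf (1 without mutant plate 2, 2 without wild-type plate 4), 1 to 2 for genotype 24 hpf (2 without wild-type plate 1), 251 to 333 for stage wt 3.5 to 8 hpf, 259 to 358 for stage mut 3.5 to 8 hpf, 245 to 282 for stage wt 8 to 24 hpf and 53 to 227 for stage mut 8 to 24 hpf (53 without 24 hpf mutant plate 1). It gave 0 to 2 for genotype by stage 8 minus 3.5 hpf (2 without 3.5 hpf mutant plate 4) and 0 to 1 for genotype by stage 24 minus 8 hpf (1 without 8 hpf mutant plate 1).

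Lists past the threshold with an estimated correlation and with fry were 0 and 0 for genotype at 3.5 and 8 hpf, 1 and 1 at 24 hpf, 0 and 7 for wild type 3.5 to 8 hpf, 1 and 6 for mutant, 0 and 8 for wild type 8 to 24 hpf, 0 and 2 for mutant, and 0 and 0 for both changes of the genotype difference. The ribosomal_protein list, genotype 8 hpf, turned to −0.0467 without mutant plate 1 and was 0.284 without it and the small plates; the ribosomal_protein list, genotype by stage 24 minus 8 hpf, turned to 0.13 without it.

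The germ plasm share 3.5 hpf, mutant minus wild type, turned to −0.0863 without h1m and ranged from −0.0452 (without mutant plate 2; also negative without mutant plate 3) to 0.811 without single plates. The germ plasm share 8 hpf ranged from −1.37 to −0.357 and germ plasm share 24 hpf from −0.784 to −0.356. The germ plasm positive cells 3.5 hpf difference was −10.4 without plates of fewer than 10 cells and ranged to −2.26. For germ plasm positive cells 8 hpf it was 4.21 without small plates and mutant plate 1, and ranged from −12.5 to 4.55 (without wild-type plate 2; positive also without wild-type plate 4 or mutant plate 1). The germ plasm positive cells 24 hpf difference ranged from −24.3 to −10.4. The germ plasm co-variation 3.5 hpf difference ranged from 0.0241 to 0.134, germ plasm co-variation 8 hpf from −0.276 to −0.0945 and germ plasm co-variation 24 hpf from −0.162 to 0.0855 (without mutant plate 3; positive also without wild-type plate 4).

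Of 86 followed calls of single genes, 1619 alternative values were 1526 on the same side, 93 weaker and 0 reversed; of 77 uncalled ones, 1548 values were 1501 the same, 35 stronger and 12 reversed. The reversed log2 values were at 24 hpf between genotypes ccnb1 0.16, tnnc2 −0.12 and rac1 0.17 in cluster 8 alone, h1m 0.0348 in cluster 7 alone, and dla 0.0391 without wild-type plate 4 (lowest −0.302, without plate 2). At 8 hpf they were gra 1e-04 with heterozygous wells added and cldnd 0.0135 without small plates and mutant plate 1, and at 3.5 hpf krt18 0.0521 by voom. From 8 to 24 hpf they were hbbe3 −0.0397 and mdm2 −0.37 in the wild type by voom, and hbbe3 0.0566 in the mutant without 24 hpf mutant plate 3 (lowest −0.487, without 8 hpf mutant plate 3).

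Genotypes share plate numbers only as numbers: correlations of same-numbered plates ran from −0.17 to 0.156 at 3.5 hpf, −0.123 to 0.301 at 8 hpf and −0.407 to 0.317 at 24 hpf, 0 stages had all pairs above 0.1, and 2, 2 and 1 plates correlated best with their own number. With the plate number as a replicate block 2, 0 and 1 genes passed for genotype 3.5 hpf, genotype 8 hpf and genotype 24 hpf, the same genes, with adjusted p of 0.0379 for zgc:113886, 0.0467 for zgc:100951 and 0.0366 for col2a1a; dla between genotypes at 24 hpf was 0.10.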

Other observations

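Of the results below, the values of the 2 week plate and of the clusters carry no test.

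Germ cells at 2 weeks post fertilization came from 1 plate with 76 cells, so values are given without a test beside wild-type plates at 24 hpf (mean ± SD, n = 5), for the genes of largest difference among 162 compared. The Piwi gene piwil1, which acts in piRNA silencing, stood at 2.13 transcripts per cell against 0.01 ± 0.022 and was detected in 82.9% of the 2 week cells. The antioxidant enzyme gene sod1 stood at 1.62 against 0.132 ± 0.074, gapdhs at 1.08 against 0.134 ± 0.119, rbm8a at 1.45 against 0.270 ± 0.133 and calm3a at 1.63 against 0.334 ± 0.218. The Tudor and piRNA list summed to 6.29 transcripts per cell against 1.36 ± 0.643. On the other side nanos3 stood at 0.013 against 3.02 ± 2.3, hmga1a at 0.184 against 3.19 ± 0.772, ptmab at 0.408 against 3.8 ± 0.897, krt4 at 0.092 against 1.38 ± 0.904, fabp3 at 0.224 against 1.48 ± 0.420 and CABZ01111496.1 at 0.105 against 31.7 ± 11.6. Among marker lists of other tissues the muscle list stood at 0.263 against 2.57 ± 2.45, the neural list at 0.026 against 1 ± 0.369, the epidermis list at 0.579 against 3.95 ± 1.6, the mesoderm and notochord list at 0.079 against 0.097 ± 0.076 and the macrophage list at 0.026 against 0.016 ± 0.025.

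The 10 clusters largely followed stage. Clusters 1 (346 cells, led by cldnd, h1m and cth1) and 3 (99 cells) held most 3.5 hpf cells, cluster 2 held 25 cells with a median of 128 genes and 87.84 mitochondrial transcripts per cell, 24 of them from mutant plate 1 at 3.5 hpf, and cluster 4 (169 cells, led, clone names aside, by tbx16 and CABZ01111496.1) most 8 hpf cells. Cluster 5, led by apoa1a, hbae3 and apoa2, held 97 cells, among them the 48 mutant and the 48 heterozygous wells of 8 hpf mutant plate 1. The 2 week cells fell into cluster 9 (41 cells, led by piwil1 and zgc:194189) and cluster 10 (34 cells), led by sycp3, cdkn2d, dmc1 and piwil1, with 1 in cluster 7; sycp3 encodes a part of the synaptonemal complex and dmc1 a meiotic recombinase. Cluster 3 was led by zgc:100951 and zgc:113886, the genes that differed between genotypes at 3.5 hpf, so its sizes are not compared between genotypes.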
